A study of Mus musculus with 19 samples.

How the data were processed

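Bulk RNA sequencing libraries were prepared from HCC827 xenograft tumours of NCG mice with a poly-A kit that does not mark the strand, so reads of overlapping genes on opposite strands cannot be told apart by strand. Per the labels, the authors used FastQC, Trimmomatic and STAR with the human build hg38, and the versions, the counter, its annotation and any separation of mouse reads are not given in the sources used here. The deposited values are raw read counts per gene symbol, with no normalization, in 1 table of 31276 genes and 19 libraries. The labels give the mouse as the organism, while the symbols are human, so the values were read as counts of human genes. Genes with 0 counts in every library are absent from the table, and columns not used numbered 0. In 156 sets, 322 symbols had identical counts in all libraries, and the first symbol that could be named stands for its set, a rule changed after the table was seen.

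Groups followed the labels: control (n = 5), thio (n = 4), osimertinib (n = 5) and combination (n = 5). Replicate numbers follow the order of deposition and pair no samples across groups. Before the data were examined, the comparisons, the tests, 42 gene lists of 711 genes, the rule for naming genes and the alternatives were fixed. Of the list genes, 710 are in the table, 13 of them under a shorter symbol of the mitochondrial genome such as ND1. The lymphocyte and erythroid marker lists were not tested, since fewer than 3 of their genes passed the filter, which left 40 lists.

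Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by group (count minimum 10, total minimum 15) kept 16704 genes, which held at least 99.8% of the counts of each library. Libraries were scaled by TMM, and 1 quasi-likelihood fit with group means over all 19 libraries was tested for 5 pairwise contrasts and for the interaction. P values were adjusted by the Benjamini-Hochberg method over the tested genes, and an adjusted p under 0.05 was called. Fold changes are log2 with SE from the fit, and log2 CPM used a prior count of 2. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, 2-sided, adjusted over the 40 lists of each contrast. The count of members adjusted over the list alone uses the same gene p values. List medians are log2 fold changes over members past the filter, and list levels per library are means of log2 CPM. Camera was repeated with a correlation estimated from the data, and fry asked whether the members move 1 way on balance.

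For each pairwise contrast the text draws on the 10 called genes with the largest fold in each direction, among named genes with mean log2 CPM of at least 2 whose groups do not overlap. It draws also on up to 4 members of each called list with the smallest p, and on EGFR, TERT, SUCLG2, MKI67, CDKN1A, DUSP6 and AXL. For the interaction the 5 largest in each direction were taken with no rule on overlap. A subset of these genes is printed, with preference for those that kept their call without each single library. Genes named only beside an explanation or hypothesis in the last part were chosen after their values were seen.

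Library measures (mitochondrial percent and summed CPM of 271 olfactory receptor genes) were compared by 2-sided exact permutation tests, adjusted over 5 comparisons. Single shares have exact binomial 95% intervals, and a count of 0 allows up to 3 counts in a library. Both cover counting error alone, since reads without molecular identifiers are not independent molecules. Total counts of 17731752 to 35397346 per library put the 3-count floor between 0.0848 and 0.169 CPM.

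The fit was tested on simulated data after the first real fit: counts were drawn from estimated means and dispersions for the same groups, with 200 of 16704 genes changed and a list raised. It recovered 50.7 to 62.7% of genes changed 2-fold in the pairwise contrasts and 20.9% in the interaction. At 4-fold it recovered 83.3 to 92.4% and 77.3%. At most 7.58% of calls were false and no sign was wrong, which was not tested for wider changes.

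Alternatives fixed in advance were DESeq2 1.42.0, RLE and upper-quartile scaling, no filter, a stricter filter (CPM of at least 1 in 4 libraries, with 10 counts), each contrast on its 2 groups alone, limma voom with quality weights, a 2-fold minimum, a covariate of stromal markers, leaving out the 2 libraries whose title numbers stand apart, and leaving out each library in turn. Chosen after the data were seen were the fit without combination 3, combination 5 and thio 3, the mitochondrial percent or the olfactory receptor level as a covariate, removal of the mitochondrial genes, and genes at mean log2 CPM of at least 2. For each count of changed genes, 100 splits of the libraries into groups of the same sizes, the real one included, were refitted. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Gene length, GC content and positions were not used here, since the annotation at hand is for the mouse. Numbers in the titles of samples were used only to choose those 2 libraries, and doses and times were not used here.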

Results

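RNA was sequenced from tumours grown in NCG mice, an immunodeficient strain, from HCC827, a human non-small cell lung cancer line whose growth depends on a mutated EGFR. The 19 libraries formed 4 groups. They were 5 controls given vehicle (DMSO), 4 given 6-thio-dG (thio from here on), a nucleoside analogue that telomerase can build into telomeres, 5 given osimertinib, an inhibitor of mutated EGFR, and 5 given both drugs (the combination). Total counts per library ran from 22348698 to 30734539 in control, from 25322580 to 34664918 in thio, from 23068873 to 35397346 in osimertinib and from 17731752 to 27450535 in the combination. The deposited table names genes by human symbol on hg38 and gives no positions. The labels do not say that each library is a separate animal, so each p below measures the spread between these samples.

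Transcripts of the mitochondrial genome took 8.15% ± 0.835 (SD, n = 5) of the counts in control, 6.45% ± 1.07 (n = 4) in thio, 12.0% ± 3.42 (n = 5) in osimertinib and 18.6% ± 7.54 (n = 5) in the combination. By 2-sided exact permutation tests, adjusted over 5 comparisons, the share was higher than in control under osimertinib (adjusted p = 0.0397, unadjusted p = 0.0159) and under the combination (adjusted p = 0.0397, unadjusted p = 0.00794). It was also higher in the combination than in thio (adjusted p = 0.0397, unadjusted p = 0.0238). The differences between thio and control (adjusted p = 0.0595, unadjusted p = 0.0476) and between the combination and osimertinib (adjusted p = 0.103, unadjusted p = 0.103) did not pass these exact tests. The highest share, 30.2% (exact binomial 95% interval 30.1 to 30.2), was that of combination 5, and combination 3 had 20.9% (20.9 to 20.9). Counts in 271 olfactory receptor genes, which are transcribed mainly in sensory neurons of the nose, summed to 4.99 ± 3.07 CPM in control, 13.4 ± 6.48 in thio, 14.8 ± 3.57 in osimertinib and 25.2 ± 11.2 in the combination. Against control these sums were higher under thio (exact permutation adjusted p = 0.0265), osimertinib (adjusted p = 0.0198) and the combination (adjusted p = 0.0198). Combination 5 (39.5 CPM), combination 3 (33.5 CPM) and thio 3 (22.8 CPM) had the highest sums of their groups, and the counts of changed genes are also given without these 3 libraries.

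**Figure D1:**
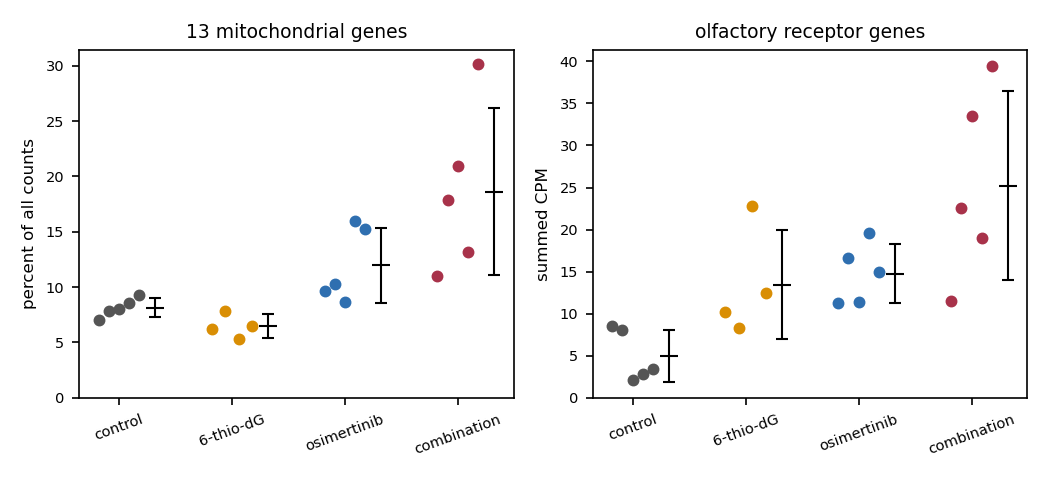
Percent of counts from the mitochondrial genome and summed CPM of olfactory receptor genes, 1 point per library, with the mean and SD of each group. Mitochondrial percents lay between 7.04 and 9.29 in control and between 11.0 and 30.2 in the combination.

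**Figure D2:**
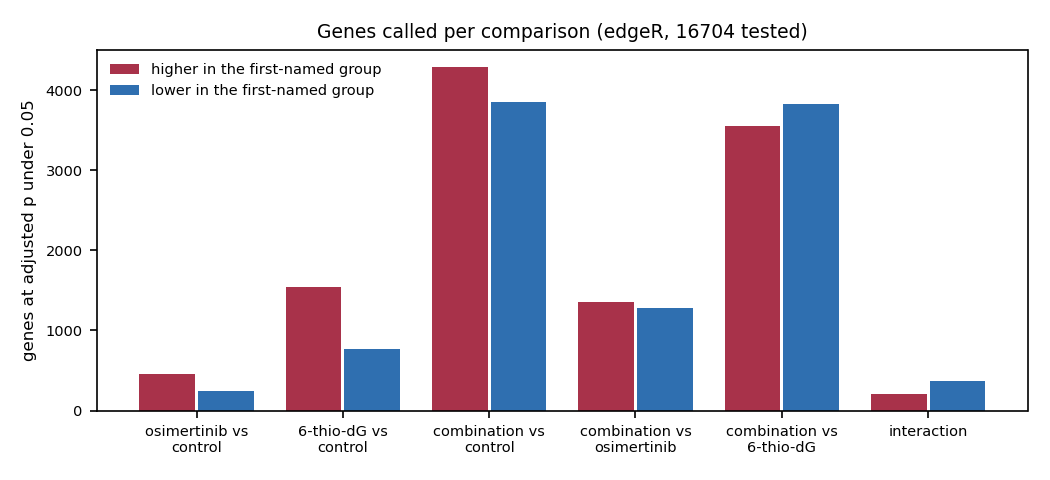
Number of genes called higher or lower (edgeR, adjusted p under 0.05) in each comparison, of 16704 tested. The combination against control had 8139 calls and osimertinib against control had 695.

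Osimertinib was compared with control to ask which transcripts differed in tumours under EGFR inhibition alone. Genes of squamous differentiation, the keratin and desmosome programme of stratified epithelia, fell: 11 of 16 measured members were lower (13 adjusted over the list alone) and 5 did not pass the test. The injury-associated keratin KRT6A had a log2 fold change of -5.05 ± 0.68 (adjusted p = 0.0015), with SE over n = 5 and 5 libraries. The desmosomal cadherin DSG3 had -4.17 ± 0.63 (adjusted p = 0.0023) and the basal keratin KRT14 -3.31 ± 0.60 (adjusted p = 0.00573). The squamous list median was -1.56 (camera adjusted p = 1.4e-17), and this call held with an estimated correlation (adjusted p = 0.0435). PI3, a protease inhibitor of inflamed epithelia, fell as well, -2.99 ± 0.57 (adjusted p = 0.00724). So did S100A9, an inflammatory calcium-binding protein, -2.17 ± 0.39 (adjusted p = 0.00517), and the complement component C3, -2.02 ± 0.37 (adjusted p = 0.00612). Among the genes that rose were the noncoding RNA LINC02532, 2.89 ± 0.34 (adjusted p = 0.00046), and the potassium channel KCNJ13, 2.48 ± 0.36 (adjusted p = 0.00225). FXYD2, a regulator of the sodium pump, rose by 2.05 ± 0.25 (adjusted p = 0.00046). TTLL9, a tubulin-modifying enzyme of cilia, rose by 2.01 ± 0.30 (adjusted p = 0.0023) and ATG9B, a membrane protein of autophagy, by 1.89 ± 0.37 (adjusted p = 0.00767). In each of these genes every osimertinib library lay beyond every control library.

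Several further lists moved under osimertinib by camera while few of their members passed on their own. Glycolysis fell in 3 of 18 genes, 6 adjusted over the list alone. Its members had a median of -0.42 (adjusted p = 7.74e-09, or adjusted p = 0.57 with an estimated correlation). Mesenchymal transition fell in 2 of 14, 7 adjusted over the list alone. The list had a median of -0.58 (adjusted p = 0.000315, or adjusted p = 0.588 with an estimated correlation). Fibroblast markers had 1 gene higher and 1 lower of 18, or 2 and 7 adjusted over the list alone, and the lower one was the collagen gene COL5A1, -1.32 ± 0.25 (adjusted p = 0.00646). This list, with a median of -0.46 (adjusted p = 0.00622, or adjusted p = 0.614 with an estimated correlation), was lost without control 3 (adjusted p = 0.0966). Alveolar differentiation rose in 3 of 15 genes, 3 adjusted over the list alone, among them the water channel AQP5, 3.25 ± 0.58 (adjusted p = 0.00517), which has few counts. The alveolar list, with a median of 0.50 (adjusted p = 0.00527, or adjusted p = 0.614 with an estimated correlation), was lost without control 5 (adjusted p = 0.0752).

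The mitochondrial genome was higher under osimertinib in 1 of 13 genes, 1 adjusted over the list alone. It had a median of 0.53 (adjusted p = 0.000571, or adjusted p = 0.701 with an estimated correlation). Camera also called hypoxia lower, with a median of -0.48 (adjusted p = 0.000315, or adjusted p = 0.664 with an estimated correlation). The stress programme of ATF4 had a median of -0.33 (adjusted p = 0.000184, or adjusted p = 0.422 with an estimated correlation). Cytosolic ribosomal proteins had a median of -0.23 (adjusted p = 0.000119, or adjusted p = 0.701 with an estimated correlation), and -0.12 without control 3, still called. The NF-kB and inflammatory cytokine list had a median of -0.55 (adjusted p = 0.000571, or adjusted p = 0.701 with an estimated correlation). Cholesterol synthesis had a median of -0.23 (adjusted p = 0.00064, or adjusted p = 0.664 with an estimated correlation). Interferon response had a median of -0.49 (adjusted p = 0.00064, or adjusted p = 0.704 with an estimated correlation), and was lost without control 2 (adjusted p = 0.136). Adjusted over the list alone, 3 hypoxia, 2 ATF4 and 2 interferon genes were lower.

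The purine handling list fell in 1 of 19 genes, adenosine deaminase, ADA, at -0.68 ± 0.12 (adjusted p = 0.00392). The list had a median of -0.10 (adjusted p = 0.0353, or adjusted p = 0.614 with an estimated correlation). Its call was lost without control 3, control 5, osimertinib 2, osimertinib 4 or osimertinib 5 (highest adjusted p = 0.0966). The unfolded protein response had a median of -0.13 (adjusted p = 0.0431, or adjusted p = 0.715 with an estimated correlation). It was lost without control 1, osimertinib 4 or osimertinib 5 (highest adjusted p = 0.138). Skeletal muscle markers, which a tumour block can carry from the host, were lower in 2 of 13 genes, 11 adjusted over the list alone. They had a median of -2.27 (adjusted p = 0.000184, or adjusted p = 0.614 with an estimated correlation). Their mean log2 CPM was 3.40 ± 1.97 (SD, n = 5) in control and 2.15 ± 0.38 (n = 5) in osimertinib. ERK pathway output, the feedback genes downstream of EGFR, did not differ by the test (median -0.01, adjusted p = 0.952), nor did DNA replication (median -0.09, adjusted p = 0.156) or mitosis (median -0.03, adjusted p = 0.65).

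When the mitochondrial share was added as a covariate, 8 of the 15 lists called under osimertinib lost their calls. Among them the unfolded protein response turned to a median of 0.12 (adjusted p = 0.176), purine handling to 0.00470 (adjusted p = 0.396) and the mitochondrial genome to -0.0489 (adjusted p = 0.212). Interferon response (adjusted p = 0.0716), NF-kB (adjusted p = 0.0846), cholesterol synthesis (adjusted p = 0.333), fibroblast (adjusted p = 0.138) and alveolar genes (adjusted p = 0.111) kept their direction.

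Of the 7 genes fixed in advance, the cell cycle inhibitor CDKN1A fell under osimertinib, -0.96 ± 0.25 (adjusted p = 0.0365), and this call was lost without control 2, control 3, control 4, osimertinib 1, osimertinib 2, osimertinib 4 or osimertinib 5 (highest adjusted p = 0.101). The other 6 did not pass the test. EGFR had -0.08 ± 0.17 (adjusted p = 0.845), the ERK phosphatase DUSP6 -0.17 ± 0.22 (adjusted p = 0.729) and the proliferation marker MKI67 -0.03 ± 0.21 (adjusted p = 0.961). The receptor AXL had -0.61 ± 0.31 (adjusted p = 0.295), the succinyl-CoA ligase subunit SUCLG2 0.08 ± 0.17 (adjusted p = 0.84) and telomerase reverse transcriptase, TERT, 1.28 ± 0.61 (adjusted p = 0.248). TERT had 0 to 27 counts per library in all groups, so its differences were not well resolved at this depth. In all, 451 genes were higher and 244 lower under osimertinib, 695 of 16704 tested (4.16%), of which 337 and 147 changed at least 2-fold. Among genes at mean log2 CPM of at least 2 the higher and lower calls were equal, 156 each. DESeq2 called 1201. The count moved by over 1.5 times without control 3 (249), control 4 (303), osimertinib 1 (401), osimertinib 2 (321), osimertinib 4 (217) or osimertinib 5 (415). It was 1154 without combination 3, combination 5 and thio 3, which enter through the shared estimate of spread.

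Thio was compared with control to ask what the telomerase-directed nucleoside did alone. Genes of the NF-kB and inflammatory cytokine list rose: 18 of 20 were higher (19 adjusted over the list alone) and 2 did not pass. The cytokine IL6 had a log2 fold change of 3.79 ± 0.62 (adjusted p = 0.00123) with SE over n = 4 and 5 libraries, the neutrophil-attracting chemokine CXCL1 3.06 ± 0.50 (adjusted p = 0.00115) and the inhibitor of apoptosis BIRC3 2.11 ± 0.31 (adjusted p = 0.000975). The list median was 2.63 (camera adjusted p = 1.71e-15; adjusted p = 0.77 with an estimated correlation). RIGI, a sensor of viral RNA, rose by 2.57 ± 0.44 (adjusted p = 0.00157). Genes of the hypoxia list rose too, 15 of 17 (15 adjusted over the list alone), with a median of 1.46 (camera adjusted p = 3.29e-15; adjusted p = 0.642 with an estimated correlation). They included the vasodilator peptide ADM, 2.97 ± 0.44 (adjusted p = 0.000975), and the pyruvate dehydrogenase kinase PDK1, 1.87 ± 0.29 (adjusted p = 0.000975).

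Glycolysis rose in 8 of 18 genes, with 8 higher and 1 lower adjusted over the list alone. It had a median of 0.43 (adjusted p = 8.38e-05, or adjusted p = 0.861 with an estimated correlation). PFKFB3 rose by 1.90 ± 0.34 (adjusted p = 0.00172) and hexokinase HK2 by 2.02 ± 0.37 (adjusted p = 0.00225). LDHA, 0.79 ± 0.20 (adjusted p = 0.0134), and PGK1, 0.98 ± 0.25 (adjusted p = 0.0149), rose as well, but not without thio 3 (adjusted p = 0.0888 and 0.104). Other genes with large rises were the amino acid transporter SLC6A14, 4.33 ± 0.67 (adjusted p = 0.000989), and the drug-metabolising CYP3A5, 4.30 ± 0.59 (adjusted p = 0.000975). Among the largest falls were FLRT2, an adhesion protein, -1.88 ± 0.35 (adjusted p = 0.00225), and the chemokine CXCL14, -1.80 ± 0.37 (adjusted p = 0.00445). The transcription factor SPI1 had -1.58 ± 0.24 (adjusted p = 0.000989). From SLC6A14 to SPI1, each of these genes was separated between all thio and all control libraries.

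The DNA replication list was lower under thio in 1 of 25 genes, with a median of -0.29 (adjusted p = 0.000123, or adjusted p = 0.861 with an estimated correlation), and -0.44 without thio 2. The gene was the checkpoint adaptor CLSPN, -0.85 ± 0.23 (adjusted p = 0.0196), lost without control 3, thio 1 or thio 3 (highest adjusted p = 0.0779), and without combination 3, combination 5 and thio 3 together (adjusted p = 0.0565). Mitosis was lower in 1 of 24 genes, the kinesin KIF20A at -0.75 ± 0.17 (adjusted p = 0.00731). The list, with a median of -0.29 (adjusted p = 0.00735, or adjusted p = 0.874 with an estimated correlation), was lost without control 1 or control 5 (highest adjusted p = 0.0848). Fibroblast markers had 1 gene higher and 6 lower of 18, or 1 and 8 adjusted over the list alone. They had a median of -0.80 (adjusted p = 0.00109, or adjusted p = 0.861 with an estimated correlation). The collagen gene COL1A1, -0.92 ± 0.24 (adjusted p = 0.0167), and smooth muscle actin, ACTA2, -1.12 ± 0.29 (adjusted p = 0.0158), were lost without control 3 or thio 3 (highest adjusted p = 0.0696 and 0.0647), COL1A1 also without the 3 libraries together (adjusted p = 0.0613). Skeletal muscle markers were lower in 2 of 13, 5 adjusted over the list alone, and averaged 2.17 ± 0.74 log2 CPM (SD, n = 4). Their list, with a median of -1.96 (adjusted p = 0.00838, or adjusted p = 0.861 with an estimated correlation), was lost without control 1, control 3 or thio 4 (highest adjusted p = 0.0786). Telomerase and shelterin genes, the list nearest to the drug's target, did not differ by the test (median -0.13, adjusted p = 0.42). Of the p53 targets 4 were higher and 3 lower of 22, and the list was not called (median 0.23, adjusted p = 0.637).

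Of the genes fixed in advance, EGFR rose under thio, 0.56 ± 0.18 (adjusted p = 0.0476), a call lost without control 3, control 4, control 5, thio 1, thio 3, thio 4, osimertinib 1, osimertinib 2, osimertinib 5, combination 2, combination 3 or combination 4 (highest adjusted p = 0.237), and without combination 3, combination 5 and thio 3 together (adjusted p = 0.18). TERT -1.54 ± 0.80 (adjusted p = 0.199), SUCLG2 0.25 ± 0.18 (adjusted p = 0.38) and MKI67 -0.05 ± 0.22 (adjusted p = 0.899) did not pass the test. Nor did CDKN1A 0.35 ± 0.26 (adjusted p = 0.398), DUSP6 0.07 ± 0.23 (adjusted p = 0.874) and AXL -0.67 ± 0.33 (adjusted p = 0.182). In all, 1548 genes were higher and 774 lower under thio, 2322 in total (13.9%), and 771 and 225 changed at least 2-fold. With upper-quartile scaling 55.6% of the calls were higher, against 66.7% with TMM. The count was 1232 without control 3, 1390 without thio 1, 736 without thio 3, 910 without combination 3, combination 5 and thio 3, and 790 when the 2 groups were fitted alone.

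**Figure D3:**
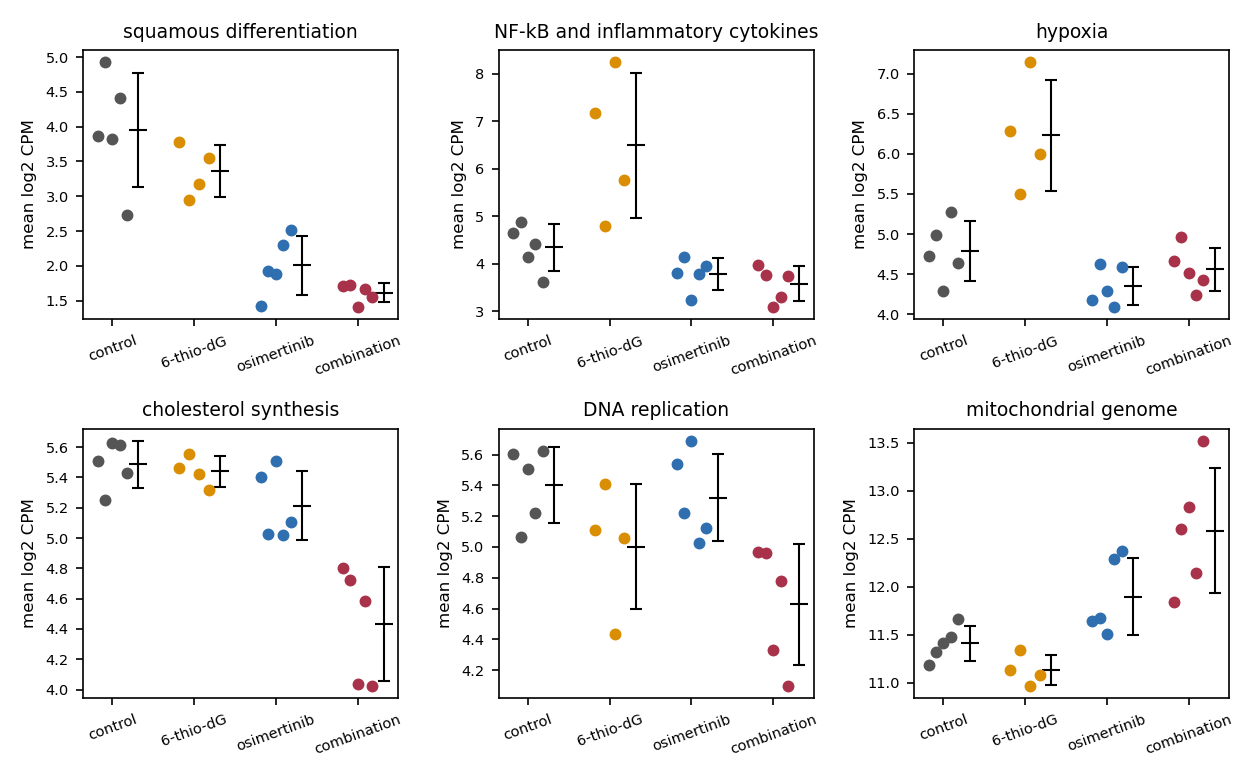
Mean log2 CPM of the members of 6 gene lists, 1 point per library, with the mean and SD of each group. The NF-kB list averaged 6.49 ± 1.53 in thio (n = 4) and 4.34 ± 0.49 in control (n = 5), and the cholesterol list 4.43 ± 0.38 in the combination and 5.49 ± 0.15 in control (n = 5 each).

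The combination was compared with control to ask what both drugs together left in the tumours. Cholesterol synthesis genes fell, 20 of 21 with 1 higher. The reductase DHCR7 had a log2 fold change of -1.41 ± 0.25 (adjusted p = 0.000274), with SE over n = 5 and 5 libraries. Squamous differentiation fell in 13 of 16 genes, with KRT6A at -5.84 ± 0.71 (adjusted p = 1.52e-05). DNA replication fell in 20 of 25 genes (24 adjusted over the list alone), the helicase subunit MCM2 by -1.43 ± 0.25 (adjusted p = 0.000267). All 13 measured genes of the mitochondrial genome rose, ND1 by 1.66 ± 0.28 (adjusted p = 0.000201). Among the largest falls were the matrix protease MMP1, -5.24 ± 0.69 (adjusted p = 3.19e-05), and S100A9, -3.81 ± 0.43 (adjusted p = 8.07e-06). LINC02532, 4.36 ± 0.35 (adjusted p = 6.77e-07), and ATG9B, 3.45 ± 0.39 (adjusted p = 8.07e-06), were among the largest rises.

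By camera, cholesterol synthesis had a median of -0.91 (adjusted p = 6.96e-10, or adjusted p = 0.475 with an estimated correlation). Squamous differentiation had a median of -2.05 (adjusted p = 2.47e-07, or adjusted p = 0.475 with an estimated correlation). DNA replication had a median of -0.73 (adjusted p = 4.54e-07, or adjusted p = 0.475 with an estimated correlation), and the mitochondrial genome a median of 1.26 (adjusted p = 1.88e-06, or adjusted p = 0.475 with an estimated correlation). Adjusted over the list alone, 20 cholesterol, 13 squamous and 13 mitochondrial genes had the direction of their list. The mitochondrial share of counts, 18.6% ± 7.54 (SD, n = 5) against 8.15% ± 0.835 in control, moved with each of these groups.

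Glycolysis fell in 16 of 18 genes (16 adjusted over the list alone). It had a median of -0.70 (adjusted p = 7.4e-06, or adjusted p = 0.475 with an estimated correlation). The unfolded protein response fell in 13 of 15 (13 adjusted over the list alone). This list had a median of -0.58 (adjusted p = 0.000105, or adjusted p = 0.475 with an estimated correlation). The TCA cycle fell in 14 of 18 (14 adjusted over the list alone), with a median of -0.48 (adjusted p = 0.000177, or adjusted p = 0.475 with an estimated correlation). Interferon response fell in 17 of 25 (18 adjusted over the list alone). Interferon genes had a median of -1.01 (adjusted p = 0.000296, or adjusted p = 0.607 with an estimated correlation). The lysosome and autophagy list had 9 genes lower and 1 higher of 19 (9 and 1 adjusted over the list alone). Its genes had a median of -0.39 (adjusted p = 0.0023, or adjusted p = 0.475 with an estimated correlation), and -0.25 without combination 5, still called. Purine handling fell in 12 of 19 (12 adjusted over the list alone). Purine genes had a median of -0.56 (adjusted p = 0.0023, or adjusted p = 0.475 with an estimated correlation). The ATF4 programme had 9 lower and 2 higher of 18 (9 and 2 adjusted over the list alone). Its members had a median of -0.55 (adjusted p = 0.00962, or adjusted p = 0.475 with an estimated correlation).

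Mesenchymal transition had 8 genes lower and 1 higher of 14 (9 and 1 adjusted over the list alone). Fibronectin, FN1, fell, -1.72 ± 0.26 (adjusted p = 8.04e-05), while the mesenchymal repressor ZEB1 rose, 1.07 ± 0.21 (adjusted p = 0.000664). The list, with a median of -0.62 (adjusted p = 0.0249, or adjusted p = 0.476 with an estimated correlation), was lost without control 3 or control 5 (highest adjusted p = 0.0739). NF-kB and inflammatory cytokines fell in 7 of 20 (6 adjusted over the list alone). This list, with a median of -0.85 (adjusted p = 0.0275, or adjusted p = 0.681 with an estimated correlation), was lost without combination 3 or combination 4 (highest adjusted p = 0.0622). Fibroblast markers had 11 lower and 2 higher of 18 (11 and 2 adjusted over the list alone). That list, with a median of -0.89 (adjusted p = 0.0302, or adjusted p = 0.476 with an estimated correlation), was lost without control 3, combination 1, combination 2 or combination 5 (highest adjusted p = 0.0905). Hypoxia (median -0.28, adjusted p = 0.269), p53 targets (median -0.16, adjusted p = 0.0732) and ERK output (median -0.24, adjusted p = 0.134) were not called.

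When the mitochondrial share was a covariate, the unfolded protein response turned to a median of 0.0185 (adjusted p = 0.602) and the mitochondrial genome to -0.0493 (adjusted p = 0.665). Glycolysis (adjusted p = 0.211), the TCA cycle (adjusted p = 0.478), lysosome and autophagy (adjusted p = 0.131) and NF-kB genes (adjusted p = 0.398) lost their calls, as did mesenchymal (adjusted p = 0.0848) and fibroblast genes (adjusted p = 0.211). Leaving out combination 3, combination 5 and thio 3 moved the medians of the mitochondrial genome to 0.79, the unfolded protein response to -0.37, the TCA cycle to -0.29 and glycolysis to -0.47, all still called. Fibroblast markers were then not called (adjusted p = 0.0586).

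Of the genes fixed in advance, CDKN1A fell under the combination, -1.74 ± 0.26 (adjusted p = 8.03e-05). DUSP6 fell, -0.56 ± 0.22 (adjusted p = 0.0402), but not without control 2, control 4, combination 2, combination 3, combination 4 or combination 5 (highest adjusted p = 0.184), nor without combination 3, combination 5 and thio 3 together (adjusted p = 0.189). EGFR -0.23 ± 0.17 (adjusted p = 0.283), SUCLG2 -0.32 ± 0.17 (adjusted p = 0.131) and MKI67 -0.37 ± 0.21 (adjusted p = 0.148) did not pass the test. Nor did AXL -0.32 ± 0.31 (adjusted p = 0.41) and TERT 1.21 ± 0.62 (adjusted p = 0.113). In all, 4288 genes were higher and 3851 lower, 8139 in total (48.7%), and 2303 and 756 changed at least 2-fold. Among genes at mean log2 CPM of at least 2 the balance turned, with 2272 higher and 3443 lower. With upper-quartile scaling 63.4% of the calls were higher, against 52.7% with TMM, and the median of all tested genes was 0.13 in place of 0.02. With no filter that median was 0.27. No library left out alone moved the count by over 1.5 times, but it was 4660 without combination 3, combination 5 and thio 3 and 175 with the mitochondrial share as a covariate.

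**Figure D4:**
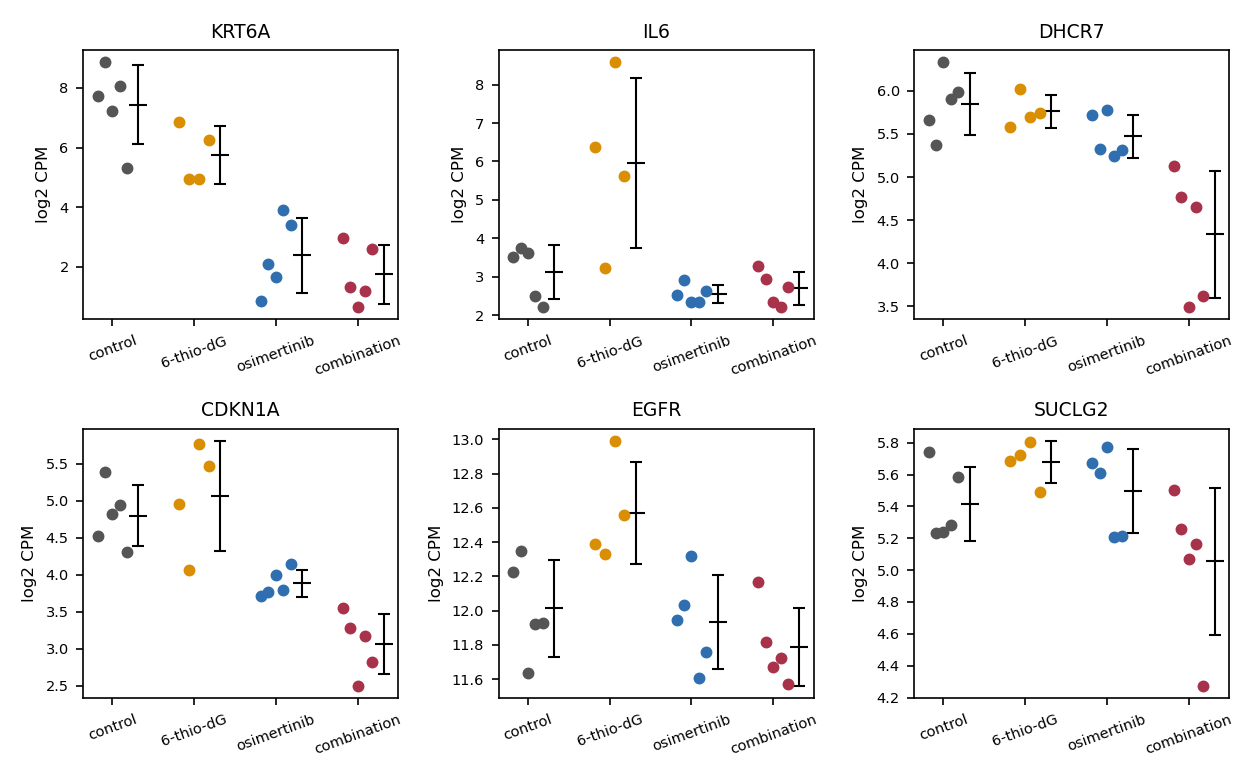
Log2 CPM of KRT6A, IL6, DHCR7, CDKN1A, EGFR and SUCLG2, 1 point per library, with the mean and SD of each group. KRT6A lies lower in both groups given osimertinib than in control, and IL6 lies higher in thio.

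The combination was compared with osimertinib to ask what thio added under EGFR inhibition. Cholesterol synthesis genes were lower, 17 of 21 (19 adjusted over the list alone). The isomerase IDI1 had a log2 fold change of -0.74 ± 0.15 (adjusted p = 0.01), with SE over n = 5 and 5 libraries, and the sterol sensor INSIG1 -1.12 ± 0.24 (adjusted p = 0.0113). DNA replication was lower in 14 of 25 genes (21 adjusted over the list alone), with CCNE2 at -0.98 ± 0.21 (adjusted p = 0.011) and MCM2 at -1.13 ± 0.25 (adjusted p = 0.0117). The mitochondrial genome was higher in 5 of 13 genes (13 adjusted over the list alone), and the mitochondrial share of counts was 18.6% ± 7.54 (SD, n = 5) against 12.0% ± 3.42. The tight junction gene CLDN2, -2.05 ± 0.37 (adjusted p = 0.00608), fell. TMEM178A, 1.86 ± 0.30 (adjusted p = 0.00521), PKD1L2, 1.68 ± 0.24 (adjusted p = 0.00424), and the cytochrome CYP2E1, 1.72 ± 0.32 (adjusted p = 0.00734), rose.

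By camera against osimertinib, cholesterol synthesis had a median of -0.80 (adjusted p = 2.69e-11, or adjusted p = 0.486 with an estimated correlation). DNA replication had a median of -0.66 (adjusted p = 1.07e-10, or adjusted p = 0.486 with an estimated correlation), and the mitochondrial genome a median of 0.70 (adjusted p = 2.14e-05, or adjusted p = 0.486 with an estimated correlation), or 0.39 without combination 5. The unfolded protein response was lower in 5 of 15 genes (10 adjusted over the list alone), with a median of -0.48 (adjusted p = 4.7e-05, or adjusted p = 0.486 with an estimated correlation). The TCA cycle was lower in 3 of 18 (13 adjusted over the list alone), with a median of -0.34 (adjusted p = 5.9e-05, or adjusted p = 0.486 with an estimated correlation). Lysosome and autophagy genes were lower in 6 of 19 (8 adjusted over the list alone), the lysosomal membrane protein LAMP1 by -0.76 ± 0.18 (adjusted p = 0.0147). They had a median of -0.33 (adjusted p = 0.00138, or adjusted p = 0.486 with an estimated correlation), and -0.21 without combination 5. Purine handling was lower in 5 of 19 (7 adjusted over the list alone), with a median of -0.36 (adjusted p = 0.00825, or adjusted p = 0.486 with an estimated correlation). Interferon response was lower in 3 of 25 (1 adjusted over the list alone), with a median of -0.43 (adjusted p = 0.00825, or adjusted p = 0.736 with an estimated correlation). NRF2 targets were lower in 3 of 16 (7 adjusted over the list alone), with a median of -0.22 (adjusted p = 0.0187, or adjusted p = 0.486 with an estimated correlation). Homologous recombination was lower in 3 of 18 (4 adjusted over the list alone), with a median of -0.33 (adjusted p = 0.0187, or adjusted p = 0.736 with an estimated correlation).

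ERK output was lower in 3 of 19 genes (3 adjusted over the list alone), the transcription factor ETV4 by -0.63 ± 0.14 (adjusted p = 0.0111). It had a median of -0.27 (adjusted p = 0.0287, or adjusted p = 0.652 with an estimated correlation). The ERK call was lost without osimertinib 3 or combination 3 (highest adjusted p = 0.132). Mitosis had a median of -0.33 (adjusted p = 0.023, or adjusted p = 0.736 with an estimated correlation). It was lost without osimertinib 3 or combination 5 (highest adjusted p = 0.108). Nuclear OXPHOS was lower in 6 of 28, with a median of -0.16 (adjusted p = 0.0349, or adjusted p = 0.736 with an estimated correlation). This call was lost without osimertinib 1, osimertinib 4 or combination 5 (highest adjusted p = 0.121). Glycolysis had a median of -0.28 (adjusted p = 0.0466, or adjusted p = 0.736 with an estimated correlation). Its call was lost without control 2, control 3, control 5, osimertinib 1, osimertinib 2, osimertinib 3, combination 3, combination 4 or combination 5 (highest adjusted p = 0.193). Airway secretory and mucin genes were lower in 2 of 9 (4 adjusted over the list alone), with a median of -0.48 (adjusted p = 0.0456, or adjusted p = 0.486 with an estimated correlation). That call was lost without control 2, any thio library, osimertinib 2, osimertinib 4, combination 1 or combination 2 (highest adjusted p = 0.0863), and without combination 5 the median was -0.74.

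Leaving out combination 3, combination 5 and thio 3 moved the median of the mitochondrial genome to 0.26, the unfolded protein response to -0.26, the TCA cycle to -0.17 and lysosome and autophagy to -0.15. Purine handling went to -0.17, homologous recombination to -0.17 and interferon response to -0.27, and these 7 lists were still called. ERK output (adjusted p = 0.147), mitosis (adjusted p = 0.408), nuclear OXPHOS (adjusted p = 0.118) and glycolysis (adjusted p = 0.919) were not. The same 4 lists (adjusted p = 0.483, 0.552, 0.0675 and 0.434, with glycolysis turned to 0.0519) and the mitochondrial genome (adjusted p = 0.455) were not called with the mitochondrial share as a covariate.

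CDKN1A was lower in the combination than under osimertinib, -0.78 ± 0.26 (adjusted p = 0.0445), a call lost without control 3, control 4, thio 1, any osimertinib library, combination 2, combination 3, combination 4 or combination 5 (highest adjusted p = 0.129). SUCLG2 -0.41 ± 0.17 (adjusted p = 0.105), EGFR -0.15 ± 0.17 (adjusted p = 0.557) and TERT -0.08 ± 0.57 (adjusted p = 0.937) did not pass the test. Nor did MKI67 -0.34 ± 0.21 (adjusted p = 0.245), DUSP6 -0.39 ± 0.22 (adjusted p = 0.203) and AXL 0.29 ± 0.31 (adjusted p = 0.524). In all, 1352 genes were higher and 1280 lower, 2632 in total (15.8%), and 447 and 123 changed at least 2-fold. Of those at mean log2 CPM of at least 2, 948 were higher and 1214 lower. With upper-quartile scaling 64.8% of the calls were higher, against 51.4% with TMM. With no filter the median of all genes was 0.11. The count was 908 without osimertinib 1, 1140 without osimertinib 2, 537 without osimertinib 3, 4693 without combination 1, 1700 without combination 2, 571 without combination 3 and 492 without combination 5. Without combination 3, combination 5 and thio 3 together 6 genes were called, among them CLDN2 and PKD1L2, and the other called genes named in this comparison lost their calls.

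The combination was compared with thio to ask what osimertinib added. All 20 members of the NF-kB and inflammatory cytokine list were lower. The chemokine CXCL8 had a log2 fold change of -4.98 ± 0.65 (adjusted p = 3.82e-05), with SE over n = 5 and 4 libraries and the interleukin IL1A -5.08 ± 0.66 (adjusted p = 3.82e-05). All 18 glycolysis genes were lower as well, HK2 by -2.92 ± 0.39 (adjusted p = 3.83e-05) and PGK1 by -1.90 ± 0.25 (adjusted p = 3.83e-05). Hypoxia was lower in 16 of 17 genes, ADM by -3.25 ± 0.44 (adjusted p = 4.61e-05) and ERO1A by -2.05 ± 0.23 (adjusted p = 1.79e-05). PTGS2, the inducible cyclooxygenase, fell, -5.89 ± 0.81 (adjusted p = 4.87e-05), as did S100A9, -4.86 ± 0.45 (adjusted p = 4.35e-06). TTLL9, 3.60 ± 0.34 (adjusted p = 4.35e-06), and ODAD1, a docking protein of ciliary dynein, 3.05 ± 0.32 (adjusted p = 8.88e-06), rose. All 13 mitochondrial genome members were higher, with 18.6% ± 7.54 (SD, n = 5) of counts against 6.45% ± 1.07 (n = 4).

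By camera against thio, the NF-kB list had a median of -4.08 (adjusted p = 5.27e-13, or adjusted p = 0.34 with an estimated correlation). Glycolysis had a median of -1.31 (adjusted p = 2.28e-13, or adjusted p = 0.34 with an estimated correlation), and hypoxia a median of -1.79 (adjusted p = 2.82e-10, or adjusted p = 0.34 with an estimated correlation). The mitochondrial genome had a median of 1.53 (adjusted p = 1.79e-09, or adjusted p = 0.34 with an estimated correlation). Cholesterol synthesis was lower in 19 of 21 genes, and had a median of -0.98 (adjusted p = 2.36e-09, or adjusted p = 0.34 with an estimated correlation). Squamous differentiation was lower in 13 of 16 (14 adjusted over the list alone), KRT5 by -3.80 ± 0.70 (adjusted p = 0.000381), and had a median of -1.90 (adjusted p = 7.54e-05, or adjusted p = 0.34 with an estimated correlation). The p53 targets were lower in 9 of 22 (9 adjusted over the list alone), the pro-apoptotic BBC3 by -2.80 ± 0.47 (adjusted p = 0.000191). They had a median of -0.33 (adjusted p = 0.0212, or adjusted p = 0.34 with an estimated correlation). The unfolded protein response was lower in 11 of 15, with a median of -0.80 (adjusted p = 3.64e-06, or adjusted p = 0.353 with an estimated correlation). The ATF4 programme had 11 genes lower and 1 higher of 18, with a median of -0.83 (adjusted p = 0.000126, or adjusted p = 0.34 with an estimated correlation). Interferon response was lower in 15 of 25, with a median of -1.01 (adjusted p = 0.00013, or adjusted p = 0.571 with an estimated correlation). The TCA cycle was lower in 11 of 18, with a median of -0.38 (adjusted p = 0.000722, or adjusted p = 0.555 with an estimated correlation).

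Lysosome and autophagy genes were lower than under thio in 11 of 19, with a median of -0.59 (adjusted p = 0.0013, or adjusted p = 0.353 with an estimated correlation). ERK output had 10 genes lower and 1 higher of 19, with a median of -0.50 (adjusted p = 0.0179, or adjusted p = 0.555 with an estimated correlation). Purine handling had 10 lower and 1 higher of 19, with a median of -0.39 (adjusted p = 0.024, or adjusted p = 0.387 with an estimated correlation). The BCL2 family was lower in 6 of 13, with a median of -0.43 (adjusted p = 0.0197, or adjusted p = 0.387 with an estimated correlation). It was lost without thio 3 (adjusted p = 0.0582). DNA replication was lower in 9 of 25, with a median of -0.32 (adjusted p = 0.0291, or adjusted p = 0.761 with an estimated correlation). It was lost without thio 2, combination 3 or combination 5 (highest adjusted p = 0.227), and was -0.53 without thio 3. Airway secretory genes had 6 lower and 1 higher of 9, with a median of -1.29 (adjusted p = 0.0325, or adjusted p = 0.353 with an estimated correlation). They were lost without thio 1, thio 2, thio 3 or combination 2 (highest adjusted p = 0.129). Adjusted over the list alone, 20 NF-kB, 18 glycolysis, 16 hypoxia, 19 cholesterol, 15 interferon, 11 ERK and 8 BCL2 genes were lower.

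Leaving out combination 3, combination 5 and thio 3 moved the median of lysosome and autophagy genes to -0.21, p53 targets to -0.16, ERK output to -0.26, the TCA cycle to -0.19 and interferon response to -0.62, all still called. The BCL2 family was then not called (adjusted p = 0.0892). With the mitochondrial covariate DNA replication turned to 0.13 (adjusted p = 0.245), the TCA cycle to 0.13 (adjusted p = 0.262), the unfolded protein response to 0.11 (adjusted p = 0.65) and the mitochondrial genome to -0.14 (adjusted p = 0.217). The p53 targets (adjusted p = 0.0628), ERK output (adjusted p = 0.85), purine handling (adjusted p = 0.565), lysosome and autophagy (adjusted p = 0.512) and the BCL2 family (adjusted p = 0.65) also lost their calls.

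CDKN1A was lower in the combination than under thio, -2.08 ± 0.27 (adjusted p = 3.82e-05), and so was EGFR, -0.79 ± 0.18 (adjusted p = 0.00216). SUCLG2 was lower by -0.57 ± 0.18 (adjusted p = 0.0163), and with the mitochondrial share as a covariate its log2 fold change turned to 0.30. TERT was higher, 2.75 ± 0.77 (adjusted p = 0.00705), on 0 to 3 counts per thio library. DUSP6 was lower, -0.63 ± 0.23 (adjusted p = 0.0332), but not without thio 1, thio 2, combination 3, combination 4 or combination 5 (highest adjusted p = 0.103). EGFR, SUCLG2, TERT and DUSP6 lost their calls without combination 3, combination 5 and thio 3 (adjusted p = 0.0673, 0.182, 0.0565 and 0.109). MKI67 -0.32 ± 0.22 (adjusted p = 0.25) and AXL 0.35 ± 0.33 (adjusted p = 0.405) did not pass the test. In all, 3549 genes were higher and 3829 lower, 7378 in total (44.2%), and 1632 and 1028 changed at least 2-fold. At mean log2 CPM of at least 2 there were 2256 higher and 3456 lower. With upper-quartile scaling 65.5% of the calls were higher, against 48.1% with TMM, and the median of all tested genes was 0.21 in place of 0.03. The count was 3311 without combination 3, combination 5 and thio 3, and 2 with the mitochondrial share as a covariate.

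The interaction asked whether thio changed transcripts differently with osimertinib than without it, as the effect of thio under osimertinib minus its effect against control. The NF-kB and inflammatory cytokine list was lower in this difference, 15 of 20 genes (19 adjusted over the list alone), with a median of -3.00 (adjusted p = 3.8e-14, or adjusted p = 0.542 with an estimated correlation), and -1.93 without thio 3. IL1B had a log2 difference of -3.44 ± 0.66 (adjusted p = 0.0265), with SE over n = 5, 4, 5 and 5 libraries, and CXCL1 -3.36 ± 0.67 (adjusted p = 0.0265). Hypoxia was lower in 5 of 17 (10 adjusted over the list alone), ERO1A by -1.53 ± 0.31 (adjusted p = 0.0278), and had a median of -1.03 (adjusted p = 1.83e-07, or adjusted p = 0.542 with an estimated correlation). Glycolysis was lower in 3 of 18 (13 adjusted over the list alone), HK2 by -2.25 ± 0.51 (adjusted p = 0.0326), and had a median of -0.79 (adjusted p = 2.58e-07, or adjusted p = 0.542 with an estimated correlation). Cholesterol synthesis was lower in 4 of 21 (14 adjusted over the list alone), the sterol carrier STARD4 by -1.81 ± 0.34 (adjusted p = 0.0265), and had a median of -0.67 (adjusted p = 9.27e-07, or adjusted p = 0.542 with an estimated correlation). The lowest genes were PTGS2 -4.77 ± 1.00 (adjusted p = 0.0287), SLC6A14 -4.49 ± 0.89 (adjusted p = 0.0265) and CCL20 -4.37 ± 1.05 (adjusted p = 0.0347), then IL23A -4.18 ± 0.81 and CHI3L2 -3.87 ± 0.74. The highest were DNAJC15 2.86 ± 0.64 (adjusted p = 0.0324), TNNI2 2.06 ± 0.47 (adjusted p = 0.0326) and TPM2 1.99 ± 0.50 (adjusted p = 0.0406), then BIRC7 1.99 ± 0.44 and ODAD1 1.94 ± 0.41. Each of these genes lost its call without control 3, thio 1, thio 3, osimertinib 2, combination 3 or combination 5, and some without further libraries. The highest adjusted p that this gave was 0.0876, for TPM2.

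The mitochondrial genome was higher in the interaction in 12 of 13 genes adjusted over the list alone. It had a median of 1.04 (adjusted p = 1.83e-07, or adjusted p = 0.542 with an estimated correlation). Skeletal muscle markers were higher in 1 of 13 (10 adjusted over the list alone), with a median of 3.73 (adjusted p = 6.27e-05, or adjusted p = 0.542 with an estimated correlation). The unfolded protein response was lower in 2 of 15, with a median of -0.74 (adjusted p = 3.76e-05, or adjusted p = 0.542 with an estimated correlation). ERK output was lower in 1 of 19, with a median of -0.46 (adjusted p = 0.00455, or adjusted p = 0.542 with an estimated correlation), and -0.30 without osimertinib 3. Lysosome and autophagy had a median of -0.53 (adjusted p = 0.00734, or adjusted p = 0.542 with an estimated correlation), or -0.31 without thio 3. The TCA cycle had a median of -0.28 (adjusted p = 0.00737, or adjusted p = 0.769 with an estimated correlation), or -0.19 without combination 5. Airway secretory genes were lower in 1 of 9, with a median of -1.35 (adjusted p = 0.00269, or adjusted p = 0.542 with an estimated correlation). That list was lost without thio 1 (adjusted p = 0.0617). Neutrophil markers were lower in 1 of 5, with a median of -2.54 (adjusted p = 0.0185, or adjusted p = 0.542 with an estimated correlation). They were lost without thio 1, thio 3 or combination 1 (highest adjusted p = 0.114), with medians of -1.53 (thio 1), -1.59 (thio 2), -0.95 (thio 3) and -1.62 (thio 4) without each thio library. Interferon response was lower in 1 of 25, with a median of -0.47 (adjusted p = 0.0235, or adjusted p = 0.867 with an estimated correlation). It was lost without control 1, control 3, control 5, thio 1, thio 3, osimertinib 4 or osimertinib 5 (highest adjusted p = 0.219), and was -0.74 without control 2. The ATF4 programme was lower in 1 of 18, with a median of -0.48 (adjusted p = 0.0449, or adjusted p = 0.553 with an estimated correlation). It was lost without control 1, control 3, thio 1, thio 3, osimertinib 4, osimertinib 5, or any combination library except combination 2 (highest adjusted p = 0.118). Adjusted over the list alone, 8 unfolded protein response, 2 ERK, 3 airway, 3 neutrophil and 7 ATF4 genes were lower.

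Leaving out combination 3, combination 5 and thio 3 ended the interaction calls of lysosome and autophagy (median -0.15, adjusted p = 0.0888), the TCA cycle (-0.0701, adjusted p = 0.313), interferon response (-0.13, adjusted p = 0.577) and the ATF4 programme (-0.24, adjusted p = 0.295). Still called, but moved, were NF-kB (-1.95), hypoxia (-0.66), glycolysis (-0.39), the unfolded protein response (-0.31), neutrophil markers (-1.15) and the mitochondrial genome (0.52). With the mitochondrial covariate the TCA cycle turned to 0.0496 (adjusted p = 0.693) and the mitochondrial genome to -0.0830 (adjusted p = 0.786). ERK output (adjusted p = 0.404), interferon (adjusted p = 0.337), ATF4 (adjusted p = 0.0958), the unfolded protein response (adjusted p = 0.648) and lysosome and autophagy (adjusted p = 0.404) lost their calls.

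The 7 genes fixed in advance did not pass the interaction test. EGFR had -0.71 ± 0.25 (adjusted p = 0.0947), SUCLG2 -0.66 ± 0.25 (adjusted p = 0.114), CDKN1A -1.13 ± 0.37 (adjusted p = 0.0736) and TERT 1.47 ± 0.98 (adjusted p = 0.342). MKI67 had -0.29 ± 0.31 (adjusted p = 0.555), DUSP6 -0.46 ± 0.32 (adjusted p = 0.358) and AXL 0.95 ± 0.46 (adjusted p = 0.187). In all, edgeR called 207 genes higher and 369 lower, 576 in total (3.45%), with 4397 at an unadjusted p under 0.05, 1757 called by DESeq2 and 2802 by limma voom with quality weights. With upper-quartile scaling 57.3% of the calls were higher, against 35.9% with TMM. With no filter the median of all genes was -0.10 in place of -0.04. Leaving out control 3, thio 1, osimertinib 2, combination 3 or combination 5 alone gave an edgeR count of 0 (3893, 3907, 3708, 3810 and 3746 at an unadjusted p under 0.05). The count was 0 without combination 3, combination 5 and thio 3 together (2293 at an unadjusted p under 0.05). Without each other library in turn it was 383 (control 1), 930 (control 2), 178 (control 4), 88 (control 5), 1072 (thio 2), 3 (thio 3), 59 (osimertinib 1), 192 (osimertinib 3), 926 (osimertinib 4), 1100 (osimertinib 5), 2157 (combination 1), 118 (combination 2) and 61 (combination 4), and within 1.5 times without thio 4 (668).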

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

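Chosen only after the result was seen were the tests of the thio cytokine genes, their split into macrophages and neutrophils, the background-read test in its present form, the second bound of the skin test, and the demand that folds shrink in the mitochondrial test; the other tests were written before.

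The breadth of the combination result, 8139 called genes against control, was set against 3 explanations. Among 100 splits of the same libraries the real split had the most calls (1 of 100, highest other 4775), so chance alone is unlikely. Reads spread evenly outside mature transcripts would give each gene counts near those of a silent gene. When 10 times the mean olfactory receptor count of each library (0.0781 to 1.46 CPM) was taken off each gene, 86.0% of the 2272 higher genes at mean log2 CPM of at least 2 were still called higher (97.4% with the scaling computed anew). Their median log2 fold went from 0.67 (median SE 0.167) to 0.63 (SE 0.171), so a background of that size is not the whole source there. Of the 2016 higher genes below that level 14.6% were still called (17.3% with the scaling computed anew), 995 were still tested, and the median of these went from 1.38 (SE 0.354) to 0.89 (SE 0.663). These calls ended through fewer counts, so background and transcription cannot be told apart there. Shares above a bound on the rise, tested first, were set aside. The gene choice nearly fixed both tests at the higher level, so a larger background stays open. Reads of unspliced transcripts, which would follow the level of each gene, were not measured. With the mitochondrial share as a covariate 2.08% of the calls remained in direction and called (169 genes), 89.9% of the 8139 genes kept their sign, and their median log2 fold along the direction first called went from 0.80 to 0.33. The median SE was 0.193 before and 0.242 after, so the call ended through smaller folds more than wider errors; an RNA state marked by that share is consistent with the breadth. Since the share itself differs by treatment, a wide effect of both drugs on the tumours stays open, and for most genes these data do not separate it from RNA state.

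The rise of NF-kB and inflammatory cytokine genes under thio was set against 3 technical sources. Without thio 3, the library whose removal lowers it most, the list median was 1.93, 73.2% of its value of 2.63 (camera adjusted p = 1.79e-15), so 1 library does not account for it. Infiltrating myeloid cells would raise their own markers too. The 9 macrophage and myeloid markers past the filter had a median of 0.16 ± 0.33 (SE), with 2 higher and 1 lower, below a bound of 1.32 (the cytokine median divided by 2) by more than 1 SE, which argues against macrophages as the whole source. The 5 neutrophil markers had a median of 1.04 ± 0.40, within 1 SE of that bound, and none was called. Among them were S100A8 1.52, CSF3R 1.50, S100A9 1.04 and FPR1 0.95 (adjusted p = 0.126, 0.183, 0.0778 and 0.375). S100A9 went from 75.0 to 148 CPM and S100A8 from 6.96 to 19.5, while CSF3R (0.170 to 0.441) and FPR1 (0.279 to 0.513) stayed near the floor. With a median so near the bound and few counts in 2 of these genes, neutrophils and tumour cells cannot be told apart as the source. Both marker tests depend on mouse reads aligning to the human genes, which the labels do not settle. The real split had the most calls (1 of 100, 2322 against 1936 at most), so chance alone is unlikely here. An inflammatory and hypoxic response of the tumour cells to thio may explain the rise, a hypothesis found and tested on the same libraries and beside which neutrophils stay open, and the call of the list rests on the preset correlation.

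The fall of squamous genes under osimertinib was set against 2 technical sources. Host skin in the control blocks would bring genes of the upper skin layers: their mean level was 0.880 to 4.70% of that of KRT5 and KRT14 in 4 control libraries but 12.2% in control 5, from KRT10, so the bound written first, under 10% in each library, was not met. KRT1, KRT2 and LORICRIN, abundant in skin, had 0 counts in all control libraries, a value looked at after the first. It argues against skin as the source as far as mouse reads of these genes align to the human ones about as well as those of KRT5 and KRT14, which was not measured. Without control 4, whose removal weakens the fall most, the list median was -1.45 in place of -1.56, so 1 control library does not account for it. The real split had the most called genes of 100 (1 of 100, 695 against 92 at most elsewhere), and a loss of a squamous state under EGFR inhibition remains a candidate explanation.

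For the combination against osimertinib 3 of 100 splits, the real one included, had at least as many calls (2632, highest other 4310). This share is small, but chance is not excluded. The real count was 6 without combination 3, combination 5 and thio 3. For the combination against thio it was 2 of 100 (7378, highest other 7510), 1 other split having more calls. For the interaction the real split had the most calls (1 of 100, 576 against 171). Those splits shuffled all 4 groups at once, so they also break the effect of each drug alone. They cannot exclude chance for the interaction itself.

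The interaction test found differences between the effects of thio with and without osimertinib in 576 genes, a count that leaving out 1 library moved to between 0 and 2157. In edgeR it was 0 without control 3, thio 1, osimertinib 2, combination 3 or combination 5 (3893, 3907, 3708, 3810 and 3746 at an unadjusted p under 0.05; DESeq2 called 1757 with all libraries). Without the library named it was 3 (thio 3), 59 (osimertinib 1), 61 (combination 4), 88 (control 5), 118 (combination 2), 178 (control 4), 192 (osimertinib 3) and 383 (control 1). It rose to 926 (osimertinib 4), 930 (control 2), 1072 (thio 2), 1100 (osimertinib 5) and 2157 (combination 1). With an estimated correlation camera called 0 of its lists (lowest adjusted p = 0.542; 3 at an unadjusted p under 0.05; fry called 8), so the lists below rest on the preset correlation. By camera its lists had medians of -3.00 for NF-kB and inflammatory cytokines, -1.03 for hypoxia, -0.79 for glycolysis, -0.67 for cholesterol synthesis, -0.74 for the unfolded protein response and 1.04 for the mitochondrial genome. The medians were -0.46 for ERK output, -0.47 for interferon response, -0.28 for the TCA cycle, -0.48 for the ATF4 programme and -0.53 for lysosome and autophagy. Airway secretory genes had -1.35, neutrophil markers -2.54 and skeletal muscle markers 3.73. Without combination 3, combination 5 and thio 3 the calls of interferon response, the TCA cycle, the ATF4 programme and lysosome and autophagy were lost (adjusted p = 0.577, 0.313, 0.295 and 0.0888). Leaving out thio 3 alone moved NF-kB to -1.93 and lysosome and autophagy to -0.31, leaving out osimertinib 3 moved ERK output to -0.30, and leaving out combination 5 moved the TCA cycle to -0.19. Leaving out 1 library ended those of airway genes (thio 1), neutrophil markers, interferon response or the ATF4 programme (highest adjusted p = 0.0617, 0.114, 0.219 and 0.118). Single genes with the largest differences were DNAJC15 (2.86), TNNI2 (2.06), TPM2 (1.99), BIRC7 (1.99), ODAD1 (1.94), PTGS2 (-4.77), SLC6A14 (-4.49), CCL20 (-4.37), IL23A (-4.18) and CHI3L2 (-3.87). Each lost its call without control 3, thio 1, thio 3, osimertinib 2, combination 3 or combination 5 (highest adjusted p = 0.0876).

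Of 208 levels of groups tested for a library far from the rest of its group 7 had one, where chance gives 10.4. Osimertinib 5 had a telomerase and shelterin level of 4.29 mean log2 CPM, against 4.54 to 4.59 in the rest of its group. Control 2 had a receptor tyrosine kinase level of 4.68 (others 4.52 to 4.55). Osimertinib 3 had an HLA class II level of -1.01 (others 1.07 to 1.68), an alveolar level of 2.68 (3.72 to 4.11) and a fibroblast level of 3.61 (3.05 to 3.18). Combination 5 had a nuclear OXPHOS level of 5.55 (others 5.92 to 6.07). Combination 3 had a neutrophil marker level of -0.46 (others 0.33 to 0.65).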

How the results depend on the processing

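Tests chosen only after the data were seen were the fit without combination 3, combination 5 and thio 3, the mitochondrial and olfactory receptor covariates, removal of the mitochondrial genes and the restriction to genes at mean log2 CPM of at least 2; the rest were planned. Of the named genes' values under the alternatives, 2449 of 2739 kept direction and call for osimertinib against control, 1587 of 1723 for thio, 2443 of 2585 for the combination against control, 2267 of 2747 against osimertinib, 2786 of 2904 against thio and 1643 of 2195 for the interaction. Another 51 turned sign while not called in either fit, and 9 reversed with a call in at least 1. For lists 909, 1009, 1007, 974, 997 and 929 of 1080 each kept both, 98, 41, 8, 17, 23 and 65 turned sign while not called in either fit, and 18 reversed with a call in at least 1. For the changes below the cause was not tested unless said. Depth limits genes near the floor such as TERT. No paired analysis was possible because the numbers in the titles and the replicate order pair no samples.

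The count for osimertinib against control was 1201 with DESeq2, 1528 with voom weights, 451 on the 2 groups alone (fewer samples for the spread), 402 without the 2 libraries with title numbers apart (fewer samples), 312 among genes at mean log2 CPM of at least 2 (fewer genes), 1154 without combination 3, combination 5 and thio 3, 175 with the mitochondrial and 10 with the olfactory receptor covariate, and 217 to 910 leaving out 1 library. For thio against control it was 790 on the 2 groups alone, 996 at 2-fold, 910 without those 3 libraries, 0 with the olfactory receptor covariate in edgeR (2344 at an unadjusted p under 0.05; DESeq2 3145 without the covariate) and 736 to 2807 leaving out 1 library. For the combination against control it was 3059 at 2-fold, 4660 without the 3 libraries, 175 with the mitochondrial and 55 with the olfactory receptor covariate. Against osimertinib it was 5327 with voom weights, 570 at 2-fold, 6 without the 3 libraries, 0 with the mitochondrial covariate in edgeR (1846 at an unadjusted p under 0.05; DESeq2 3659 without the covariate), 247 with the olfactory receptor covariate and 492 to 4693 leaving out 1 library. Against thio it was 2660 at 2-fold, 3311 without the 3 libraries and 2 with the mitochondrial covariate. The interaction count was 1757 with DESeq2, 2802 with voom weights, 193 with the stromal covariate, 0 without the 3 libraries and 0 with the mitochondrial covariate in edgeR (2293 and 1292 at an unadjusted p under 0.05), and 0 to 2157 leaving out 1 library. With the mitochondrial covariate the 695 genes of osimertinib against control all kept their sign, with a median log2 fold along the direction first called of 1.42 in place of 1.58 and a median SE of 0.393 in place of 0.361, and 147 remained called. For the combination against osimertinib these values were 0.38 in place of 0.66 (SE 0.164 in place of 0.182), against thio 0.18 in place of 0.80 (SE 0.276 in place of 0.196, 72.6% with their sign kept) and for the interaction 0.83 in place of 1.34 (SE 0.322 in place of 0.326). Olfactory receptor counts nearly separate treated from control libraries, so that covariate removes the treatment with them.

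The number of lists called, 15, 7, 14, 15, 17 and 14 in the same order, fell with an estimated correlation to 1, 0, 0, 0, 0 and 0 in camera (3, 2, 3, 1, 4 and 3 at an unadjusted p under 0.05). With fry it was 3, 3, 21, 13, 21 and 8. With the mitochondrial covariate it was 7 for osimertinib and 9 for the combination against control.

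With the mitochondrial covariate the values below reversed. For genes of the combination against thio these were MCM2 0.00175, RRM1 0.23, DLD 0.0511, ND2 -0.14, LAMP1 0.0416, MCL1 0.16 and SUCLG2 0.30. List medians for osimertinib against control were mitochondrial genome -0.0489, unfolded protein response 0.12 and purine handling 0.00470. For the combination against control they were mitochondrial genome -0.0493, unfolded protein response 0.0185 and YAP targets 0.34, and against osimertinib glycolysis 0.0519. For the combination against thio they were DNA replication 0.13, mitosis 0.49, TCA cycle 0.13, mitochondrial genome -0.14, unfolded protein response 0.11, YAP targets 0.21, fibroblast 0.47 and neutrophil markers 0.0613. For the interaction they were mitosis 0.37, TCA cycle 0.0496 and mitochondrial genome -0.0830. With the olfactory receptor covariate CCDC26 (-0.0784) and VCAM1 (0.12) of the combination against control reversed. The mitochondrial lists follow from the construction of that covariate.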

Other observations

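Every test here was chosen only after the result was seen, because genes of these families stood among the largest folds.

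Genes of motile cilia, beyond the few named above, rose most in the combination. A list of cilium genes that left out those already seen among the 50 largest folds had 30 tested members, of which 27 rose in the combination against control. Their median log2 fold change was 1.53, against a median of 0.15 (middle 95% from -0.17 to 0.49) for random lists of like expression, a percentile of 100. Examples are the dynein chain DNAI1 at 3.06 ± 0.38 (adjusted p = 1.89e-05), the radial spoke gene RSPH4A at 2.82 ± 0.34 (adjusted p = 1.52e-05) and the ciliary regulator FOXJ1 at 1.71 ± 0.46 (adjusted p = 0.00497). Under osimertinib alone 8 of the 30 rose, with a median of 0.69 and a percentile of 100, or a median of 0.42 with 1 gene called with the mitochondrial covariate. Under thio the median was 0.26 with 3 genes called, or 0.42 with 7 called with that covariate (camera unadjusted p = 0.475 and 0.121 with an estimated correlation). Against thio the combination had a median of 1.45 with 22 genes higher, 0.60 with the covariate and 1.05 without the 3 libraries (camera unadjusted p = 0.0228, 0.0291 and 0.0185 with an estimated correlation). Against osimertinib it had 0.75 with 12 higher, 0.38 and 0.45, and the interaction 0.34 with 0 called (camera unadjusted p = 0.039, 0.0204, 0.0281 and 0.277, likewise). The rise was largest with both drugs, and a wider rise under thio alone stays open. Against control the combination had 0.92 with the covariate (5 genes called) and 1.23 without combination 3, combination 5 and thio 3 (25 of 29 called). Camera with an estimated correlation gave an unadjusted p of 0.00832.

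Of 32 tested CYP and UGT genes, enzymes of drug and steroid metabolism, 8 stood among the 50 largest folds and were left out. Of the other 24, 14 rose and 2 fell in the combination against control. Their median was 0.81, against 0.31 for random lists (middle 95% from -0.12 to 0.79), a percentile of 97.88 that lies close to the upper end of that range. With the mitochondrial covariate the median was 0.34 (edgeR called 0, with 6 at an unadjusted p under 0.05), and without combination 3, combination 5 and thio 3 it was 0.66 with 7 higher and 1 lower. Camera with an estimated correlation gave an unadjusted p of 0.12, so a wider rise is not separated from RNA state. Under thio the median was 0.17, a percentile of 83.97, which leaves a wider rise open there. Of 435 tested ZNF genes outside the 50 largest folds, mostly zinc finger repressors, 139 rose and 42 fell in the combination, with a median of 0.21 against -0.01 for random lists, a percentile of 100. This shift ended with the mitochondrial covariate (median -0.0128, 1 gene higher) and was 0.0783 without the 3 libraries, with 75 higher and 28 lower (estimated correlation p = 0.445 with all libraries). The bounds of these tests were loosened, and the genes among the 50 largest folds left out, after their first values were seen.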
